A study of Citrus sinensis with 48 samples.

How the data were processed

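RNA was measured in leaves of 2 citrus rootstock genotypes, Carrizo citrange (Car) and Cleopatra mandarin (Cleo), in 8 treatments with 3 biological replicates each, 48 libraries in all. Per the labels' protocols, total RNA was extracted with a Maxwell kit and sequenced from stranded poly(A)-selected libraries. Read alignment and quantification were done by the authors. FastQC 0.11.7, HISAT2 2.1.0 and StringTie 2.1.3b are named, per the submitters' processing notes. The gene models are those of a RefSeq annotation of sweet orange, per the file headers and gene IDs. Trimming, the strand setting and the treatment of reads that align to several places are not given in the sources used here, so genes with near-identical copies and antisense pairs are uncertain.

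The deposited table gives 30136 genes with a raw read count, an FPKM and a TPM for each library, per the file headers. The read counts deposited by the authors are whole numbers and were used for all tests. StringTie derives such counts from coverage, so they can be estimates rounded to whole numbers. The FPKM and TPM columns were not used in any test. Every per-sample column matched 1 sample. The libraries held 40294831 to 58392998 counts. CPM are scaled to library totals after TMM.

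Gene names were taken from the table. Of its gene IDs, 23878 matched a RefSeq gene table of another sweet orange assembly (DVS_A1.0), which was used only for that match and gave no coordinates. For 478 genes whose symbol was not unique the feature ID was added. Of the genes, 24543 are protein-coding and 3089 had 0 counts in all libraries.

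Counts were tested in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr over the 16 groups, which left 23721, and libraries were scaled by TMM. Dispersions were estimated with estimateDisp (robust) and a quasi-likelihood model with 16 group means was fitted to all 48 libraries (glmQLFit robust, 32 residual degrees of freedom, glmQLFTest). The common biological coefficient of variation was 11.2%. P-values were adjusted by Benjamini-Hochberg within each comparison and called below 0.05. The 30 planned comparisons began with each of 7 stresses against CT in each genotype and Cleo against Car under CT. They also held the genotype difference of each response (Cleo minus Car) and the departures of combinations. For a pair, the departure is from the sum of its parts in log2. For the triple it is the factorial term, the triple minus its pairs plus its single stresses minus CT. Whether replicates came from separate plants or from pools is not given beyond the word biological, so p-values measure only the spread between these samples. A fitted fold change of a gene with at most 3 counts in a group depends on the prior count.

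Gene lists were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2, a preset inter-gene correlation of 0.01 and at least 5 members, and again with an estimated correlation. The 37 lists were defined by words in gene descriptions and hold heat shock proteins and their factors, chaperones, hormone, osmolyte, photosynthesis, pigment, defence, wall and ribosome genes, and markers of dividing, vascular, epidermal and guard cells. Adjustment was over 518 tests for the 14 stress comparisons, 555 for the interactions and 111 for added comparisons. A gene can stand in more than 1 list, and a description can place a gene wrongly.

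The genes named in the text follow a rule. For each stress comparison they are the 3 largest rises and 3 largest falls among called genes with a mean log2 CPM of at least 3, a description that is not uncharacterized, and 3 stressed libraries that do not overlap the 3 controls. Of each list described, up to 3 called members with the lowest p could be named. For genotype differences and departures the rule is the same without the overlap condition. Genes already given for another comparison were mostly left out.

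The comparisons, tests, lists, naming rule and settings to compare were fixed before the data were examined. These settings were DESeq2 1.42.0 (Wald test and, separately, its size factors), no filter on low counts, the replicate number as a block, only the libraries of the comparison, each library left out in turn, the estimated correlation, and agreement over called genes only. After seeing the data, 3 comparisons were added (HL against HS in each genotype, and the genotype difference of the HL and HS departure), with list tests of interactions, list medians at a floor of 3 counts, and fits without ribosomal RNA and chloroplast genes. Also added were fits with the column mark of 11 libraries as a term and fits of unmarked or marked libraries alone. Other splits of the libraries were refitted, 10 for comparisons of 6 libraries and up to 100 drawn for the others. The number drawn was raised from 25 after a first run.

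Tests were run on counts of 22307 genes simulated from the real means and library sizes. For comparisons 200 changed and for departures 400 (200 scored), far below the real calls, so rates need not carry over. Of genes changed 1.5, 2 and 4-fold, 63.6%, 79.1% and 100% were recovered for WS against CT in Car, with 5.4% false calls. The genotype difference under WS recovered 33.3%, 64.2% and 89.1% (1.6% false), the departure of WS and HL in Car 36.4%, 80.6% and 97% (3.8% false), and the triple departure in Car 10.6%, 52.2% and 89.4% (4.3% false). Unchanged groups gave 0 calls against CT for HS in Car and HL in Cleo. Replicate pairs differed by a chi-square of 4.20 to 131.6 per gene, so none was counted as a copy. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.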

Results

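The series holds 48 leaf libraries from 2 citrus genotypes and 8 treatments, 16 groups of 3 biological replicates. Carrizo citrange (Car below) is a hybrid rootstock of sweet orange and trifoliate orange, and Cleopatra mandarin (Cleo) is a mandarin used as a rootstock. The treatments were control (CT), water stress (WS), high light (HL), heat stress (HS) and the 4 combinations WS+HL, WS+HS, HL+HS and WS+HL+HS. Durations, light intensities and temperatures are not given in the sources used here. The libraries had 21139 to 23087 genes detected. Ribosomal RNA genes took 0.457% to 5.39% of the counts and chloroplast genes 0.152% to 2.24%. The mean ribosomal RNA share was highest in Cleo under WS+HL+HS (3.55% ± 2.00, SD, n = 3).

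Unless stated otherwise, a gene is followed by its log2 fold change ± SE against CT of the same genotype. The SE, back-calculated from the test's F, can be too small near 0 counts. A level is the mean normalised CPM ± SD with n = 3. Genes passed at adjusted p below 0.05 in edgeR's quasi-likelihood test over 23721 genes. Lists show members that rose and fell, the median log2 fold change and the list test's adjusted p under a small preset correlation between genes. The adjusted p with a correlation estimated from the data, noted as estimated, is added wherever not below 0.05. Adjusted over the list alone, counts of called members moved by at most 8 genes in Car and 5 in Cleo under any stress. Where libraries near 0 counts move a median by more than 0.1, the median with such genes at a floor of 3 counts follows. Genes given as the largest rises and falls had stressed libraries that did not overlap the controls.

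All 48 libraries correlated best with a library of their own group, and the lowest correlation within a group was 0.979. The first principal component held 44.9% of the variance and parted the genotypes, with Car between -177 and -90.6 and Cleo between 89.2 and 168.6. The second (17.4%) parted treatments with water stress from the others, and the third (11.5%) held HL+HS and WS+HL+HS of Cleo at its upper end (128.2 to 141.1) and CT of Cleo at its lower (-99.6 to -96). Of the libraries, 11 carry an unexplained mark in their column names, spread over CT, HL, HS and WS+HL in Car and CT, HL+HS and WS+HL+HS in Cleo. In the 6 groups that hold both kinds, pairs of different marks differed by a median chi-square of 58.9 per gene, against 13.98 in pairs of the same mark. With the mark as a term in the fit, 2116 genes were higher and 1724 lower in marked libraries, 122 of them at least 2-fold. Counts from unmarked libraries alone are therefore given where each group keeps one. CT of Car and HL+HS of Cleo keep a single unmarked library, so counts that use them, among them all for Car and for genotype differences, assume that it varies like libraries of the other groups. So do counts from marked libraries, except that for HS in Car.

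**Figure D1:**
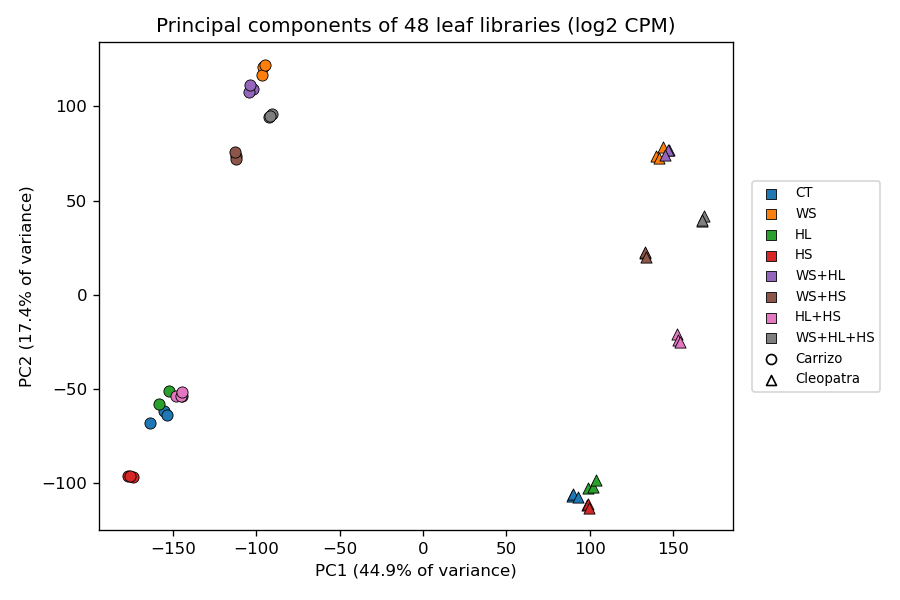
Principal component scores of the 48 libraries (log2 CPM, centred by gene; axes in score units with the percent of variance), coloured by treatment with 1 symbol per genotype. PC1 (44.9%) separates Car from Cleo and PC2 (17.4%) the libraries with water stress, above 0, from those without, below 0.

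**Figure D2:**
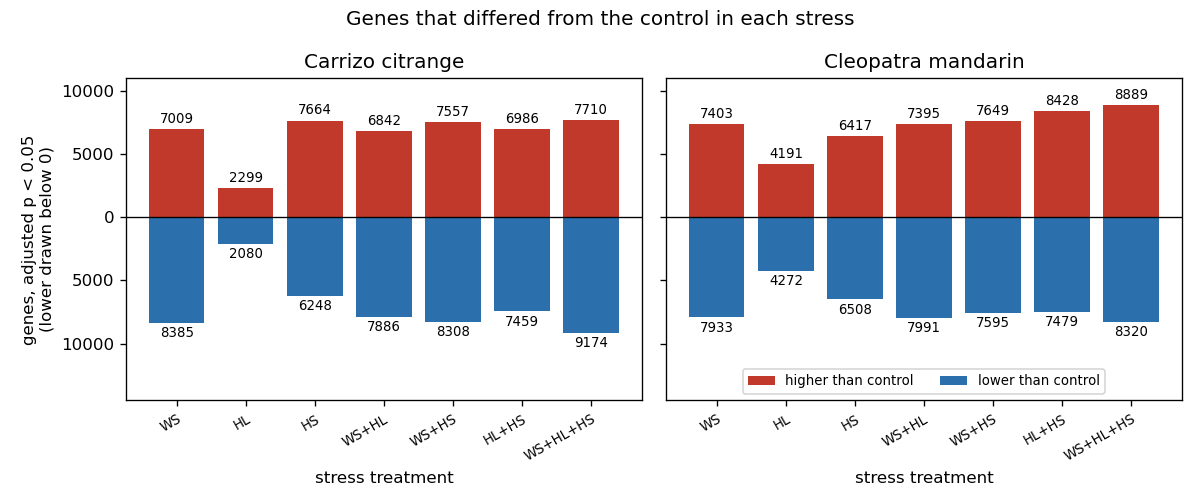
Number of genes higher (above 0) and lower (below 0) than CT at an adjusted p below 0.05 for each of 7 stresses in Car and Cleo (3 against 3 libraries each, 23721 genes tested). HL alone changed the fewest genes in both genotypes, 4379 in Car and 8463 in Cleo, and WS+HL+HS the most, 16884 and 17209.

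The response of each genotype to water deficit was read from WS against CT. The largest rise in both genotypes was in a late embryogenesis abundant protein, LEA46-like (LOC102628020), of a family that protects proteins in drying cells. It went from 12.3 ± 1.90 to 5015 ± 117 CPM in Car (8.66 ± 0.45) and from 1.52 ± 0.176 to 5185 ± 213 CPM in Cleo (11.74 ± 0.53). In Car it was followed by asparagine synthetase 1 (LOC102628580, 8.13 ± 0.18) and a UPF0098 protein (LOC102620461, 7.04 ± 0.27), and in Cleo by UDP-glycosyltransferase 76B1-like (LOC102606711, 10.38 ± 0.22) and the hydrophobic peptide ESI3 (LOC102622890, 8.23 ± 0.17). The largest falls in Car were in HOTHEAD-like (LOC102630146, -6.26 ± 0.36), whose Arabidopsis relative acts in cuticle formation, a GDSL esterase (LOC102618547, -5.47 ± 0.28) and MARD1 (LOC102612013, -5.45 ± 0.15). In Cleo they were in auxin-binding protein ABP19a (LOC102627199, -6.43 ± 0.15), the small subunit of ADP-glucose pyrophosphorylase, an enzyme of starch synthesis (LOC102625409, 14.2 ± 2.82 against 866 ± 2.57 CPM, -5.93 ± 0.12), and succinylbenzoate-CoA ligase (LOC102610951, -5.74 ± 0.15). Each of these had an adjusted p of 3.96e-17 or lower.

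Of the 36 genes of dehydration protection (dehydrins, LEA proteins and raffinose-family enzymes), in Car 27 of 36 rose and 3 fell (median 2.56, adjusted p = 1.14e-08). In Cleo 23 rose and 3 fell (median 2.40, 1.66 at the floor, adjusted p = 3.39e-06). Their members included low-temperature-induced 65 kDa protein (LOC102609060, 5.07 ± 0.09 in Car and 4.14 ± 0.09 in Cleo) and stachyose synthase (LOC102611645, 6.73 ± 0.18 in Car). Of the abscisic acid signalling genes, in Car 19 of 33 rose and 8 fell (median 0.28, adjusted p = 0.0042, adjusted p = 0.12 estimated). In Cleo 21 rose and 4 fell (median 0.22, adjusted p = 0.00435, adjusted p = 0.12 estimated). The protein phosphatases 2C that rose, such as PP2C 24 (LOC102611031, 4.81 ± 0.09 and 5.02 ± 0.09), are negative regulators of that pathway. Proline metabolism, a source of the osmolyte proline, held 7 genes: in Car 5 of 7 rose and 2 fell (median 1.11, adjusted p = 0.0433, adjusted p = 0.12 estimated). In Cleo 5 rose and 1 fell (median 1.05, adjusted p = 0.0117, adjusted p = 0.0596 estimated). The synthetic enzyme delta-1-pyrroline-5-carboxylate synthase (LOC102619471) stood at 2.11 ± 0.09 in Car and 1.27 ± 0.09 in Cleo. Autophagy genes, which run the recycling of cell contents, moved together: in Car 21 of 23 rose and 1 fell (median 0.60, adjusted p = 1.38e-05). In Cleo 20 rose and 0 fell (median 0.84, adjusted p = 5.37e-06).

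Genes of the chloroplast fell. Of the photosystem and light harvesting genes, in Car 1 of 39 rose and 36 fell (median -1.59, adjusted p = 6.24e-12, adjusted p = 0.301 estimated). In Cleo 1 rose and 36 fell (median -2.55, adjusted p = 8.6e-17, adjusted p = 0.201 estimated). Chlorophyll a-b binding protein CP24 (LOC102609463) stood at -2.88 ± 0.09 in Car and -3.77 ± 0.10 in Cleo. Of the Calvin cycle genes, in Car 1 of 15 rose and 12 fell (median -1.09, adjusted p = 0.00121, adjusted p = 0.384 estimated). In Cleo 1 rose and 11 fell (median -1.38, adjusted p = 0.000339, adjusted p = 0.339 estimated). Fructose-1,6-bisphosphatase (LOC102628345) stood at -1.91 ± 0.13 in Car and -3.51 ± 0.14 in Cleo. Of the chloroplast ribosomal proteins, in Car 1 of 43 rose and 42 fell (median -1.06, adjusted p = 2.36e-09, adjusted p = 0.39 estimated). In Cleo 1 rose and 41 fell (median -1.60, adjusted p = 1.5e-12, adjusted p = 0.307 estimated). STAY-GREEN (LOC102625350), which starts chlorophyll breakdown, rose by 3.80 ± 0.08 in Car and 5.70 ± 0.08 in Cleo. Of the terpene synthases, in Car 2 of 33 rose and 28 fell (median -3.17, adjusted p = 9.39e-06). In Cleo 1 rose and 21 fell (median -3.48, -1.53 at the floor, adjusted p = 0.00136, adjusted p = 0.135 estimated). Auxin response genes fell in Cleo (17 of 80 rose and 49 fell, median -1.30, -1.16 at the floor, adjusted p = 0.00171), with auxin response factor 4 (LOC102613600) at -5.15 ± 0.10. Aquaporins, channels for water, were called in Car, where 6 of 31 rose and 19 fell (median -1.70, adjusted p = 0.00286, adjusted p = 0.221 estimated), among them NIP2-1-like (LOC102612686, -4.94 ± 0.12).

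In total 7009 genes were higher and 8385 lower in Car, and 7403 and 7933 in Cleo. Unmarked libraries alone gave 14146 and 15341 called genes. The difference between genotypes, tested as an interaction, was called in 8557 genes (8346 in unmarked libraries). PIP2-2-like aquaporin LOC102608729 fell in Car from 30 ± 1.1 to 3.86 ± 0.383 CPM and rose in Cleo from 28.6 ± 2.48 to 378 ± 17.6 CPM (difference 6.68 ± 0.14). A second PIP2-2-like gene (LOC102609769, 5.44 ± 0.12) and UGT76B1-like (LOC102606711, 8.21 ± 0.26) were also higher in the Cleo response. Asparagine synthetase 1 (LOC102628580, -5.72 ± 0.21), inositol oxygenase 1 (LOC102618274, -5.45 ± 0.14) and a suppressor of disruption of TFIIS (LOC102622497, -4.78 ± 0.22) were lower. Of the aquaporins, 14 of 31 were higher and 3 lower (median 0.88, 1.00 at the floor, adjusted p = 0.00028, adjusted p = 0.171 estimated) in the Cleo response, and of the photosystem genes 0 of 39 were higher and 29 lower (median -0.71, adjusted p = 4.84e-10, adjusted p = 0.395 estimated). Dividing-cell markers were higher (34 of 87 higher, 5 lower, median 0.51, adjusted p = 0.00167, adjusted p = 0.205 estimated).

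High light alone was the mildest stress by gene count, and its largest changes were in heat shock genes and, in Cleo, their cofactor BAG6. In Car a 17.4 kDa class I heat shock protein (LOC102626248) went from 0.301 ± 0.230 to 158 ± 35.9 CPM (9.0 ± 0.28), HSP70-5-like (LOC102625591) rose by 8.87 ± 0.19 and a small heat shock protein (LOC102630544) by 8.64 ± 0.27. In Cleo the last pair rose by 11.23 ± 0.21 and 11.51 ± 0.31. The co-chaperone BAG6 (LOC102629351), a cofactor of HSP70, held 3 counts over the CT libraries of Cleo, all in replicate 1, and stood at 260 ± 12.4 CPM under HL, a ratio of 13350 (95% counting interval 4569 to 64750). This interval covers counting error only, and without that library CT holds 0 counts. Of the 62 heat shock proteins, in Car 55 of 62 rose and 1 fell (median 4.70, 4.12 at the floor, adjusted p = 7.08e-109). In Cleo 54 rose and 1 fell (median 4.90, 4.40 at the floor, adjusted p = 3.11e-69). ClpB1 (LOC102620452), which dissolves protein aggregates, rose from 67.4 ± 5.95 to 2063 ± 99.4 CPM in Car (4.94 ± 0.08) and by 6.31 ± 0.09 in Cleo. Near-identical small heat shock gene copies can share reads, so single members are uncertain.

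Heat stress transcription factors, which regulate these genes, changed as a group: in Car 10 of 22 rose and 2 fell (median 0.76, adjusted p = 1.06e-11). In Cleo 10 rose and 4 fell (median 0.36, adjusted p = 1.83e-05). HSF B-2a (LOC102626069) stood at 2.17 ± 0.06 in Car and 2.74 ± 0.06 in Cleo. Of the other chaperones and co-chaperones, in Car 28 of 111 rose and 8 fell (median 0.05, adjusted p = 4.02e-05). In Cleo 36 rose and 16 fell (median 0.12, adjusted p = 0.000275). DnaJ B13 (LOC102619066) rose by 3.54 ± 0.07 in Car and 4.15 ± 0.07 in Cleo. Genes of endoplasmic reticulum folding rose in Cleo (11 of 36 rose and 2 fell, median 0.17, adjusted p = 0.0042, adjusted p = 0.0857 estimated), and luminal-binding protein 5 (LOC102609733), a chaperone of that compartment, rose by 7.66 ± 0.26 in Car and 8.20 ± 0.26 in Cleo. Of 9 photoprotection genes, in Car 3 of 9 rose and 0 fell (median 0.19, adjusted p = 0.0329, adjusted p = 0.551 estimated). In Cleo 6 rose and 0 fell (median 0.38, adjusted p = 0.00284, adjusted p = 0.384 estimated). Early light-induced protein 1 (LOC102626141) stood at 1.59 ± 0.13 in Car and 1.92 ± 0.13 in Cleo. The Car list gave adjusted p = 0.19 without CT replicate 2 (the only unmarked one) and 0.654 without HL replicate 1 (the only marked one). Antioxidant enzymes were called in Cleo, where 19 of 32 rose and 0 fell (median 0.24, adjusted p = 6.34e-05, adjusted p = 0.296 estimated), among them cytosolic ascorbate peroxidase 2 (LOC102622372, 2.42 ± 0.11). Of the WRKY factors, many of them acting in defence, 6 of 54 rose and 22 fell (median -0.42, adjusted p = 0.000454) in Cleo. Of the chloroplast ribosomal proteins, in Car 16 of 43 rose and 0 fell (median 0.26, adjusted p = 6.34e-05, adjusted p = 0.58 estimated). In Cleo 35 rose and 0 fell (median 0.53, adjusted p = 1.22e-09, adjusted p = 0.384 estimated). Without HL replicate 1 the Car list gave adjusted p = 0.568. Markers of dividing cells were lower in Car (3 of 87 rose and 15 fell, median -0.17, adjusted p = 0.0121, adjusted p = 0.277 estimated, and adjusted p = 0.0566 without HL replicate 2).

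The largest falls in Car were in genes that plants raise when phosphate is short: the phosphodiesterase GDPD1 (LOC102608187, 10.4 ± 1.48 against 68.0 ± 4.31 CPM, -2.71 ± 0.14), SPX1 (LOC102629287, -2.21 ± 0.09) and purple acid phosphatase 8-like (LOC102618098, -1.97 ± 0.17). In Cleo GDPD1 (-3.29 ± 0.14), NAC29 (LOC102608057, -3.13 ± 0.12) and the clock gene APRR5 (LOC102631246, -2.78 ± 0.06) fell most. Adjusted p was 5.87e-12 or lower for each. In Car 2299 genes were higher and 2080 lower, and in Cleo 4191 and 4272. Unmarked libraries gave 3211 and 9115 called genes, and marked ones 2810 in Car, each Car count with 1 library in an arm. With only the 6 libraries of the comparison in the fit, Car had 1118 called genes. The interaction was called in 3659 genes, 3844 in unmarked libraries and 1790 with the 12 libraries of the comparison alone. WRKY53 (LOC102614924) was higher in the Car response (-4.10 ± 0.24). Of the heat shock proteins, 27 of 62 were higher and 2 lower (median 0.87, 0.63 at the floor, adjusted p = 2.23e-14) in the Cleo response. Of the ERF and DREB factors, 1 of 99 were higher and 30 lower (median -0.37, adjusted p = 4.95e-07). Of the other genes with the largest differences, 2 of a 21 kDa seed protein and 2 of 5.8S ribosomal RNA lost their call or turned with 1 library left out.

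Heat alone also had its largest rises in genes of heat shock proteins and, in Cleo, a cofactor of HSP70. In Car the 17.4 kDa class I proteins LOC102613214 (776 ± 86.2 against 2.09 ± 0.767 CPM, 8.53 ± 0.21) and LOC102626248 (8.24 ± 0.28) and the small heat shock gene LOC102630544 (6.78 ± 0.25) rose most, and in Cleo BAG6 (LOC102629351) did, with 8.85 ± 0.808 CPM and a ratio of 458 (95% counting interval 156.4 to 2224) to CT, followed by LOC102630544 (8.57 ± 0.28) and HSP83-like (LOC102616579, 7.42 ± 0.20). Falls were largest in Car for the wax synthase-like gene WSD1 (LOC102628692, 2.30 ± 0.241 against 104 ± 4.99 CPM, -5.50 ± 0.17), F-box PP2-B15-like (LOC112497515, -4.72 ± 0.48) and NAC29 (LOC102608057, -4.61 ± 0.14). In Cleo they were in beta-glucosidase 46-like (LOC102607393, -4.04 ± 0.14), heat shock cognate 70-2 (LOC102617514, 75.9 ± 7.85 against 1166 ± 52.3 CPM, -3.94 ± 0.09) and organ-specific protein S2-like (LOC102611808, -3.77 ± 0.40). Each had an adjusted p of 7.94e-10 or lower. Heat shock proteins as a list rose: in Car 43 of 62 rose and 8 fell (median 1.56, adjusted p = 3.05e-11, adjusted p = 0.0651 estimated). In Cleo 39 rose and 9 fell (median 0.86, adjusted p = 6.71e-07, adjusted p = 0.16 estimated).

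Photoprotection genes fell under HS: in Car 0 of 9 rose and 8 fell (median -1.45, adjusted p = 6.12e-06, adjusted p = 0.174 estimated). In Cleo 0 rose and 7 fell (median -0.87, adjusted p = 0.000969, adjusted p = 0.342 estimated). Early light-induced protein 1 (LOC102578039) stood at -2.40 ± 0.11 in Car and -2.42 ± 0.11 in Cleo. Photosystem genes rose: in Car 29 of 39 rose and 4 fell (median 0.88, adjusted p = 0.000133, adjusted p = 0.581 estimated). In Cleo 21 rose and 7 fell (median 0.44, adjusted p = 0.00171, adjusted p = 0.661 estimated). Genotypes moved apart in the cytosolic ribosomal proteins, where in Car 87 of 168 rose and 17 fell (median 0.25, adjusted p = 0.00125, adjusted p = 0.762 estimated). In Cleo 8 rose and 111 fell (median -0.38, adjusted p = 1.63e-07, adjusted p = 0.58 estimated). In Car the markers of dividing cells rose (53 of 87 rose and 14 fell, median 0.77, adjusted p = 0.00398, adjusted p = 0.197 estimated), among them cyclin-D3-1 (LOC102621853, 2.65 ± 0.14). Clock genes, read as a check of sampling time, moved in both directions in Car (8 of 22 rose and 12 fell, median -0.41, adjusted p = 0.00698, adjusted p = 0.347 estimated), with APRR5 (LOC102631246) at -1.94 ± 0.06 and LHY-like (LOC102627326) at -2.40 ± 0.09. In Cleo genes of phenylpropanoid and lignin synthesis fell (14 of 109 rose and 54 fell, median -0.58, adjusted p = 0.00113, adjusted p = 0.0545 estimated).

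In Car 7664 genes were higher and 6248 lower, and in Cleo 6417 and 6508. All 3 HS libraries of Car carry the column mark. Set against the marked CT libraries alone they gave 14354 called genes, and unmarked libraries gave 12769 in Cleo. The interaction was called in 10370 genes. HS libraries are all marked in Car and all unmarked in Cleo, so neither kind alone gives a value. Beta-amyrin synthase-like (LOC102612414, 5.70 ± 0.20) and the transporter NRT1/PTR 3.1-like (LOC102609680, 4.66 ± 0.35) were higher in the Cleo response. A salicylate methyltransferase-like gene (LOC102625129, -4.55 ± 0.33), chlorophyllase-1 (LOC102621972, -4.34 ± 0.21) and Kunitz trypsin inhibitor 2 (LOC102622270, -4.32 ± 0.19) were lower. Of the cytosolic ribosomal proteins 3 of 168 were higher and 126 lower (median -0.71, adjusted p = 1.2e-14, adjusted p = 0.433 estimated) in Cleo, and of the dividing-cell markers 5 of 87 were higher and 47 lower (median -0.82, adjusted p = 0.00017, adjusted p = 0.128 estimated).

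Since heat shock genes rose under HL, HL was set directly against HS, a comparison chosen after seeing the data. In Car 6505 genes were higher and 7619 lower under HL than under HS, and in Cleo 6046 and 6099. The 6 Cleo libraries are all unmarked, and in Car the marked libraries, 1 of them under HL, gave 12460 called genes. Of the 62 heat shock proteins, 54 of 62 were higher and 4 lower (median 2.12, adjusted p = 8.35e-20) in Car, and 51 of 62 were higher and 3 lower (median 3.31, 3.13 at the floor, adjusted p = 3.49e-31) in Cleo. Of the 9 photoprotection genes, 8 were higher and 0 lower in Car (median 1.57, adjusted p = 1.33e-06, adjusted p = 0.209 estimated) and in Cleo (median 1.22, adjusted p = 2.37e-06, adjusted p = 0.219 estimated). HSP70-5-like (LOC102625591) stood at 543 ± 68.5 CPM under HL and 34.6 ± 3.21 under HS in Car, and at 1833 ± 72.3 and 125 ± 3.81 in Cleo. Markers of dividing cells (6 of 87 higher, 61 lower, median -1.04, adjusted p = 3.71e-05, adjusted p = 0.107 estimated) and clock genes (12 of 22 were higher and 6 lower, median 0.27, adjusted p = 0.00499, adjusted p = 0.382 estimated) differed in Car, and epidermis and cuticle markers in Cleo (14 of 25 higher, 4 lower, median 0.65, adjusted p = 0.0325, adjusted p = 0.551 estimated).

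**Figure D3:**
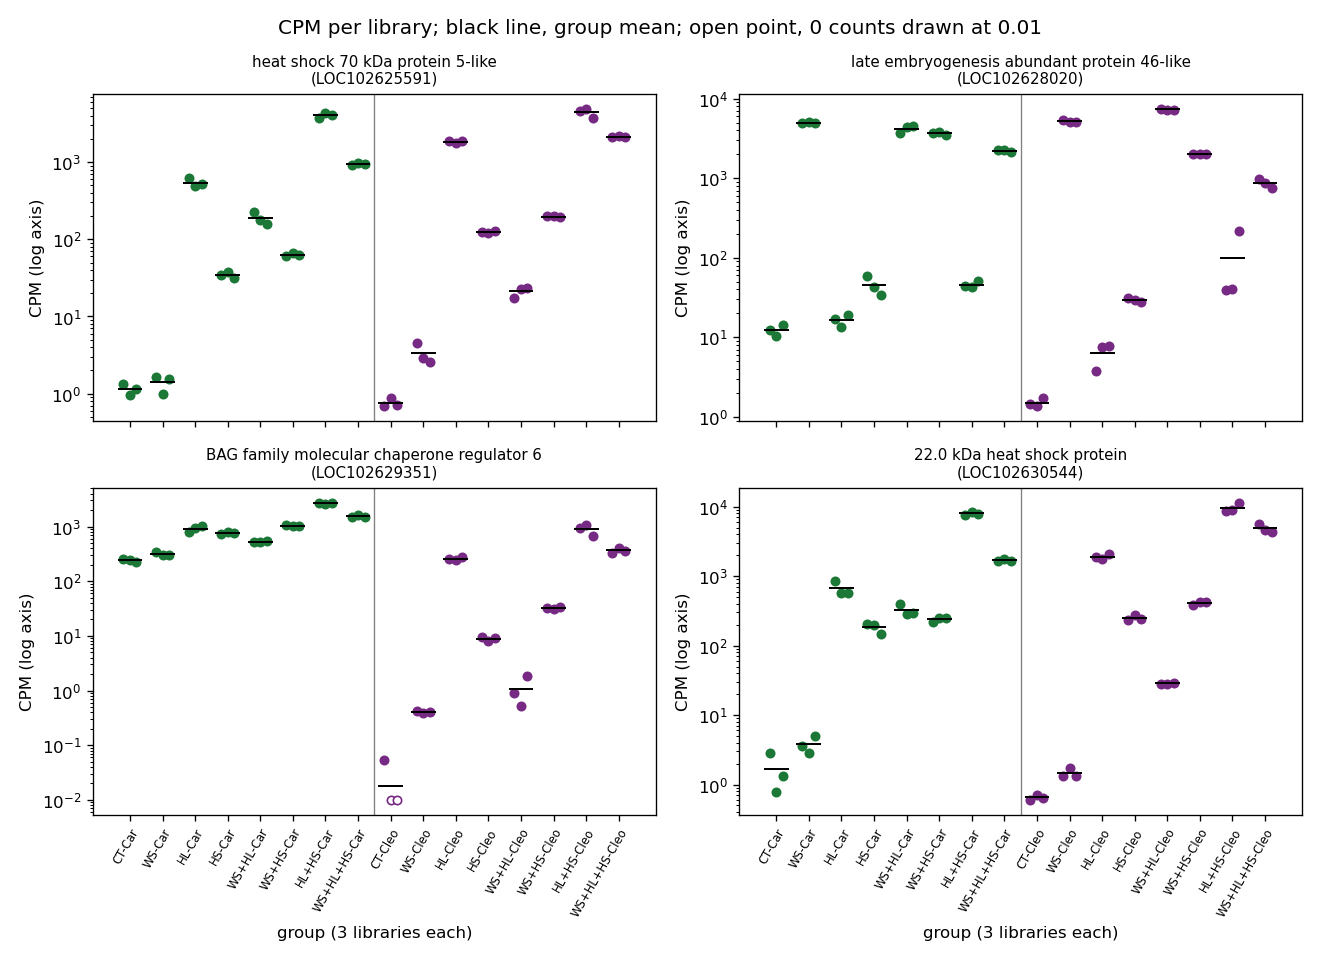
CPM (log axis) of 4 genes, HSP70-5-like, LEA46-like, BAG6 and a small heat shock protein, with 1 point per library by group (Car left, Cleo right), a black line at each group mean (n = 3) and open points for libraries at 0 counts. LEA46-like (LOC102628020) is at 12.3 CPM in CT and 5015 in WS of Car, and HSP70-5-like (LOC102625591) at 1.15 in CT and 543 in HL.

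Under WS+HL LEA46-like (LOC102628020) rose most again, with 4198 ± 464 against 12.3 ± 1.90 CPM in Car (8.41 ± 0.45) and 7349 ± 94.9 against 1.52 ± 0.176 CPM in Cleo (12.24 ± 0.53). The UPF0098 protein (LOC102620461, 8.38 ± 0.26) and LOC102626248 (8.24 ± 0.28) followed in Car, and UGT76B1-like (LOC102606711, 10.26 ± 0.22) and monooxygenase 2-like (LOC102622692, 8.82 ± 0.20) in Cleo. In Car the GDSL esterase LOC102618547 (-6.73 ± 0.31), HOTHEAD-like LOC102630146 (-6.04 ± 0.36) and an ABCG15-like transporter (LOC102626767, -5.73 ± 0.32) fell most. In Cleo ABP19a (LOC102627199, -5.97 ± 0.14), aquaporin PIP2-8 (LOC102624436, 2.43 ± 0.368 against 133 ± 14.8 CPM, -5.78 ± 0.15) and the ADP-glucose pyrophosphorylase subunit LOC102625409 (-5.59 ± 0.12) did. Adjusted p was 9.17e-17 or lower for each.

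Of the heat shock proteins, in Car 50 of 62 rose and 3 fell (median 3.58, 3.28 at the floor, adjusted p = 1.27e-21). In Cleo 41 rose and 4 fell (median 1.60, adjusted p = 1.38e-08, adjusted p = 0.12 estimated). Dehydration protection genes rose: in Car 24 of 36 rose and 3 fell (median 2.43, adjusted p = 8.9e-09). In Cleo 26 rose and 3 fell (median 2.22, 2.04 at the floor, adjusted p = 2.98e-07). Autophagy genes rose: in Car 19 of 23 rose and 0 fell (median 0.48, adjusted p = 8.69e-05). In Cleo 19 rose and 0 fell (median 0.74, adjusted p = 5.38e-06). ATG8f (LOC102611739) stood at 1.45 ± 0.11 in Car and 2.41 ± 0.11 in Cleo. In Cleo the senescence-linked NAC29 (LOC102608057) stood at 363 ± 6.20 against 19.4 ± 2.66 CPM (4.23 ± 0.10) and NAC72 (LOC102612201) at 5.97 ± 0.09. Photosystem genes fell: in Car 1 of 39 rose and 33 fell (median -1.09, adjusted p = 9.89e-09, adjusted p = 0.391 estimated). In Cleo 1 rose and 36 fell (median -1.97, adjusted p = 3.09e-13, adjusted p = 0.274 estimated).

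In Car 6842 genes were higher and 7886 lower (13275 called in unmarked and 12580 in marked libraries), and in Cleo 7395 genes were higher and 7991 lower (15513 in unmarked libraries). The interaction between genotypes was called in 9494 genes (9085 in unmarked libraries), among them caffeic acid methyltransferase-like LOC102619425 (5.84 ± 0.28), chalcone synthase 2-like (LOC102607309, -4.58 ± 0.24) and the 17.4 kDa heat shock protein LOC102626248 (-4.63 ± 0.76). Of the heat shock proteins 3 of 62 were higher and 38 lower (median -1.23, adjusted p = 3.72e-12, adjusted p = 0.0744 estimated) in the Cleo response, and of the dividing-cell markers 34 of 87 were higher and 10 lower (median 0.45, adjusted p = 0.00628, adjusted p = 0.254 estimated).

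Additivity was tested in log2 (folds multiplied, not CPM added), as the change under the combination minus the sum of the single changes. It departed from 0 in 4301 genes in Car and 5978 in Cleo (3961 and 6428 in unmarked libraries). The Car count was 6760 without HL replicate 1 and 2074 with the 12 libraries of the test alone. Heat shock genes fell short of the sum: in Car 1 of 62 were higher and 47 lower (median -1.45, adjusted p = 1.23e-33), and in Cleo 1 of 62 were higher and 48 lower (median -3.55, adjusted p = 1.33e-69). An example in Cleo was HSP70 LOC102625888 (-8.11 ± 0.17), with 2.97 ± 0.491 CPM in CT, 167 ± 20.8 in WS, 1855 ± 76.2 in HL and 375 ± 12.5 in WS+HL. HSP70-5-like (LOC102625591, -8.57 ± 0.25) fell short in Cleo, and luminal-binding protein 5 (LOC102609733, -4.54 ± 0.33) and the mitochondrial 26.5 kDa heat shock protein (LOC102624529, -4.39 ± 0.30) in Car. NAC29 (LOC102608057, 3.24 ± 0.15) and the ethylene receptor gene ETR2 (2.99 ± 0.16) exceeded the sum in Cleo, and the wall-loosening genes expansin-A1 (LOC102606649, 2.54 ± 0.31) and expansin-like B1 (LOC102624467, 2.33 ± 0.47) in Car. WRKY factors went below the sum in Car (2 of 54 were higher and 21 lower, median -0.57, adjusted p = 1.17e-07) and above it in Cleo (19 of 54 were higher and 5 lower, median 0.56, adjusted p = 0.00131). In Car the dividing-cell markers departed too (16 of 87 higher, 3 lower, median 0.22, adjusted p = 0.0272, 0.389 estimated and 0.0642 without HL replicate 2). So did clock genes (2 of 22 higher, 8 lower, median -0.23, adjusted p = 0.013, 0.415 estimated).

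Under WS+HS asparagine synthetase 1 (LOC102628580) rose most in Car, to 856 ± 23.7 against 1.34 ± 0.340 CPM (9.31 ± 0.19), followed by the UPF0098 protein (LOC102620461, 9.19 ± 0.26) and LOC102613214 (8.71 ± 0.21). In Cleo BAG6 (LOC102629351) reached 32.4 ± 1.65 CPM, a ratio of 1680 (95% counting interval 574.7 to 8151) to CT, and LEA46-like (LOC102628020, 10.38 ± 0.51) and HSP83-like (LOC102616579, 929.5 ± 18.3 against 1.1 ± 0.249 CPM, 9.74 ± 0.21) followed. Organ-specific protein S2-like (LOC102611808, -8.27 ± 0.54), germacrene D synthase-like (LOC102623066, 0.883 ± 0.105 against 94.8 ± 19.4 CPM, -6.74 ± 0.23) and beta-glucosidase 46-like (LOC102607393, -6.40 ± 0.17) fell most in Car. Proline-rich protein 4-like (LOC102619149, -7.36 ± 0.45), the cutin-related acyltransferase DCR (LOC102627030, -6.75 ± 0.37) and DMR6-like oxygenase 2 (LOC102627081, -6.61 ± 0.29) did in Cleo. Each had an adjusted p of 1.79e-15 or lower.

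The heat shock protein list rose: in Car 47 of 62 rose and 7 fell (median 1.82, adjusted p = 5.4e-11, adjusted p = 0.0686 estimated). In Cleo 48 rose and 6 fell (median 1.52, adjusted p = 2.4e-10, adjusted p = 0.0826 estimated). Dehydration protection rose: in Car 25 of 36 rose and 1 fell (median 2.46, adjusted p = 7.63e-08). In Cleo 23 rose and 6 fell (median 2.14, 1.72 at the floor, adjusted p = 7e-05, adjusted p = 0.0834 estimated). Phenylpropanoid and lignin genes fell: in Car 25 of 109 rose and 54 fell (median -0.46, adjusted p = 0.00822, adjusted p = 0.12 estimated). In Cleo 18 rose and 58 fell (median -0.56, adjusted p = 0.000615). Cinnamyl alcohol dehydrogenase 6 (LOC102617066) stood at -4.0 ± 0.14 in Car and -3.54 ± 0.12 in Cleo. Carotenoid synthesis fell: in Car 3 of 31 rose and 18 fell (median -0.51, -0.33 at the floor, adjusted p = 0.0313, adjusted p = 0.23 estimated). In Cleo 4 rose and 15 fell (median -0.34, adjusted p = 0.0311, adjusted p = 0.23 estimated). Phytoene synthase 2 (LOC102628113) stood at -3.65 ± 0.20 in Car and -4.30 ± 0.19 in Cleo. In Car the list gave adjusted p = 0.0615 with the column mark as a term. Markers of vascular cells were lower in Car (3 of 41 rose and 30 fell, median -2.45, adjusted p = 0.000372, adjusted p = 0.12 estimated) and those of epidermis and cuticle in Cleo (2 of 25 rose and 16 fell, median -1.57, adjusted p = 0.0039, adjusted p = 0.347 estimated), beside cell wall loosening genes in Car (19 of 138 rose and 73 fell, median -0.97, adjusted p = 0.00274, adjusted p = 0.136 estimated). The lists of guard cell markers, abscisic acid metabolism, and ethylene synthesis and signalling passed under no stress. Under WS+HS in Car the counts were 2 of 16 rose and 6 fell, median -0.40, adjusted p = 0.467, for the guard cell markers. They were 5 of 15 rose and 6 fell, median -0.16, adjusted p = 0.974, for abscisic acid metabolism, and 8 of 32 rose and 13 fell, median -0.16, adjusted p = 0.979, for the ethylene genes.

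In Car 7557 genes were higher and 8308 lower (14475 called in unmarked libraries), and in Cleo 7649 genes were higher and 7595 lower (15214). The genotypes differed in 9888 genes (9812 in unmarked libraries). Germacrene D synthase-like LOC102623066 was higher in the Cleo response (7.41 ± 0.30), and a seed lectin-like gene (LOC102628131, -5.74 ± 0.17), endochitinase-like LOC102628172 (-5.87 ± 0.30) and STRICTOSIDINE SYNTHASE-LIKE 4 (LOC102608831, -5.48 ± 0.49) were lower. Of the ERF and DREB factors 7 of 99 were higher and 46 lower (median -0.79, adjusted p = 8.92e-05) in Cleo, and of the vascular markers 20 of 41 were higher and 2 lower (median 1.47, 1.31 at the floor, adjusted p = 0.0129, adjusted p = 0.31 estimated). Departures from additivity were called in 8793 genes in Car, where all HS libraries are marked, and 8838 in Cleo (9716 in unmarked libraries). NCED, which codes the enzyme of the committed step of abscisic acid synthesis, fell short of the sum in Car (-3.59 ± 0.19), with 4.55 ± 0.314 CPM in CT, 152 ± 12.6 in WS, 4.40 ± 0.406 in HS and 12.3 ± 1.85 in WS+HS. A caffeic acid methyltransferase-like gene (LOC102609652, -4.59 ± 0.39) fell short too, while 21 kDa seed protein-like LOC102631364 (4.19 ± 0.44), the acetyltransferase HLS1 (LOC102617166, 3.92 ± 0.22) and WSD1-like (LOC102628692, 3.77 ± 0.21) exceeded the sum. In Cleo peroxidase 15-like (LOC102614517, 3.62 ± 0.33) and the transporter YPQ1 (LOC102626245, 3.58 ± 0.15) exceeded it, and LEA46-like (LOC102628020, -5.64 ± 0.54) fell short. Chloroplast ribosomal proteins exceeded the sum in both: 33 of 43 were higher and 0 lower (median 0.73, adjusted p = 3.99e-12, adjusted p = 0.376 estimated) in Car and 32 of 43 were higher and 0 lower (median 0.86, adjusted p = 4.99e-11, adjusted p = 0.394 estimated) in Cleo. Jasmonate genes fell short in Car (4 of 33 were higher and 17 lower, median -0.74, adjusted p = 0.00176), as did dividing-cell markers (10 of 87 higher, 34 lower, median -0.47, adjusted p = 0.00256, adjusted p = 0.225 estimated).

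The largest rises under HL+HS were in small heat shock genes in Car and in BAG6 in Cleo. LOC102626248 reached 2183 ± 146 against 0.301 ± 0.230 CPM in Car (12.78 ± 0.30) and 1261 ± 59.3 against 0.204 ± 0.194 CPM in Cleo (12.65 ± 0.31), and the small heat shock gene LOC102630544 reached 8001 ± 381 and 9672 ± 1550 CPM (12.23 ± 0.30 and 13.85 ± 0.32). LOC102613214 rose by 11.98 ± 0.24 in Car, and BAG6 (LOC102629351) reached 889 ± 202 CPM in Cleo, a ratio of 46860 (95% counting interval 16030 to 227200) to CT. WSD1-like (LOC102628692, -4.91 ± 0.17), S2-like (LOC102611808, -4.86 ± 0.43) and amino acid permease 3 (LOC102625596, -4.77 ± 0.23) fell most in Car. Beta-glucosidase 46-like (LOC102607393, 27.3 ± 3.68 against 2375 ± 255 CPM, -6.44 ± 0.16), proline-rich protein 4-like (LOC102619149, -6.33 ± 0.42) and S2-like (LOC102611808, -6.22 ± 0.49) did in Cleo. Adjusted p was 5.34e-12 or lower for each.

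Most heat shock proteins rose: in Car 55 of 62 rose and 3 fell (median 6.74, adjusted p = 2.44e-38). In Cleo 57 rose and 4 fell (median 5.80, 5.08 at the floor, adjusted p = 1.65e-26). Of their transcription factors, in Car 17 of 22 rose and 2 fell (median 1.14, adjusted p = 2.89e-06). In Cleo 17 rose and 3 fell (median 2.05, adjusted p = 8.66e-06). HSP83 (LOC102628301) rose by 7.42 ± 0.10 in Car and HSP70 LOC102625888 by 10.81 ± 0.16 in Cleo. Dehydration protection genes rose: in Car 20 of 36 rose and 5 fell (median 0.99, adjusted p = 0.00232, adjusted p = 0.174 estimated). In Cleo 22 rose and 5 fell (median 1.31, adjusted p = 0.000608, adjusted p = 0.124 estimated). Galactinol synthase 1 (LOC102616851), the first enzyme of raffinose synthesis, stood at 529 ± 13.98 against 0.262 ± 0.111 CPM in Car (10.98 ± 0.26) and at 10 ± 0.25 in Cleo. Photosystem genes went apart between the genotypes: in Car 27 of 39 rose and 3 fell (median 0.52, adjusted p = 0.000549, adjusted p = 0.622 estimated). In Cleo 3 rose and 26 fell (median -0.58, adjusted p = 0.00374, adjusted p = 0.689 estimated). Cytosolic ribosomal proteins rose: in Car 110 of 168 rose and 11 fell (median 0.50, adjusted p = 9.51e-09, adjusted p = 0.539 estimated). In Cleo 135 rose and 6 fell (median 0.67, adjusted p = 1.89e-09, adjusted p = 0.521 estimated). Pathogen defence genes rose: in Car 28 of 60 rose and 12 fell (median 0.40, adjusted p = 0.0194, adjusted p = 0.164 estimated). In Cleo 34 rose and 16 fell (median 1.38, 1.23 at the floor, adjusted p = 0.00868, adjusted p = 0.12 estimated). PR-1 (LOC102622841) stood at 3.04 ± 0.10 in Car and 4.92 ± 0.14 in Cleo. In Cleo glutathione S-transferases, which conjugate toxic compounds, rose (35 of 60 rose and 10 fell, median 1.43, adjusted p = 0.000861, adjusted p = 0.394 estimated), as did NAC factors (42 of 72 rose and 9 fell, median 0.80, adjusted p = 0.000364), while epidermis and cuticle markers fell (3 of 25 rose and 17 fell, median -1.72, adjusted p = 0.00534, adjusted p = 0.362 estimated). The ribosomal RNA share of these Cleo libraries was 2.13% ± 0.671, against 1.86% ± 1.66 in CT.

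In Car 6986 genes were higher and 7459 lower (12922 called in unmarked libraries), and in Cleo 8428 genes were higher and 7479 lower (14453 in unmarked and 14485 in marked libraries). The genotypes differed in 11873 genes (10684 in unmarked libraries). Stem-specific protein TSJT1-like (LOC102609704, 9.66 ± 0.30) was higher in the Cleo response, going from 0.245 ± 0.0155 to 78.1 ± 18 CPM against 2.05 ± 0.236 and 0.795 ± 0.0456 in Car. NRT1/PTR 3.1-like (LOC102609680, 6.82 ± 0.34) was higher too, and a lectin (LOC102630138, -5.81 ± 0.25) and Kunitz trypsin inhibitor 2 (LOC102622270, -5.31 ± 0.20) were lower. Of the photosystem genes 1 of 39 were higher and 34 lower (median -1.04, adjusted p = 5.51e-10, adjusted p = 0.398 estimated) in Cleo, and of the NAC factors 34 of 72 were higher and 5 lower (median 0.70, 0.81 at the floor, adjusted p = 0.000189). Epidermis and cuticle markers were lower (1 of 25 higher, 17 lower, median -1.40, adjusted p = 0.000649, adjusted p = 0.294 estimated).

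Departures from additivity of HL and HS were called in 6599 genes in Car, where all HS libraries are marked, and 11864 in Cleo (11379 in unmarked libraries). In Car early light-induced protein 1 (LOC102626141, 3.66 ± 0.19) and inorganic pyrophosphatase 1 (LOC102617018, 3.66 ± 0.16) exceeded the sum, and a seed lectin-like gene (LOC102628131, -4.52 ± 0.17) fell short. Small heat shock genes fell short too (LOC102626248, -4.46 ± 0.35 in Car, and LOC102630544, -6.22 ± 0.33 in Cleo). In Cleo carboxylesterase 15 (LOC102631454, 6.32 ± 0.30), extensin-2-like (LOC102608242, 6.01 ± 0.40) and salicylic acid-binding protein 2-like (LOC102612910, 5.92 ± 0.24) exceeded it. In Cleo 2 of 39 photosystem genes were higher and 33 lower (median -1.28, adjusted p = 6.05e-13, 0.325 estimated). Of 15 Calvin cycle genes 1 was higher and 12 lower (median -1.24, adjusted p = 4.91e-06, 0.24 estimated). Of 168 cytosolic ribosomal proteins 148 were higher and 0 lower (median 0.99, adjusted p = 5.97e-22, 0.328 estimated). Clock genes exceeded the sum in Car (14 of 22 higher, 4 lower, median 0.49, adjusted p = 4.48e-09). Dividing-cell markers fell short there (3 of 87 higher, 26 lower, median -0.42, adjusted p = 0.0156, 0.328 estimated and 0.0574 without HL replicate 1). The difference between the departures of Cleo and Car, tested after seeing the data, was called in 8531 genes (8254 with the mark as a term). Of the WRKY factors, 24 of 54 were higher and 2 lower (median 1.28, adjusted p = 8.86e-06) in Cleo, and of the photosystem genes 0 of 39 were higher and 29 lower (median -1.02, adjusted p = 9.23e-12, adjusted p = 0.382 estimated). Markers of dividing cells (32 of 87 higher, 2 lower, median 0.68, adjusted p = 0.00579, adjusted p = 0.247 estimated), epidermis and cuticle (2 of 25 higher, 10 lower, median -0.67, adjusted p = 0.0262, adjusted p = 0.543 estimated) and the clock (5 of 22 were higher and 12 lower, median -0.42, adjusted p = 0.0404, adjusted p = 0.551 estimated) differed too, the last pair with adjusted p of 0.209 and 0.133 with the mark as a term.

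**Figure D4:**
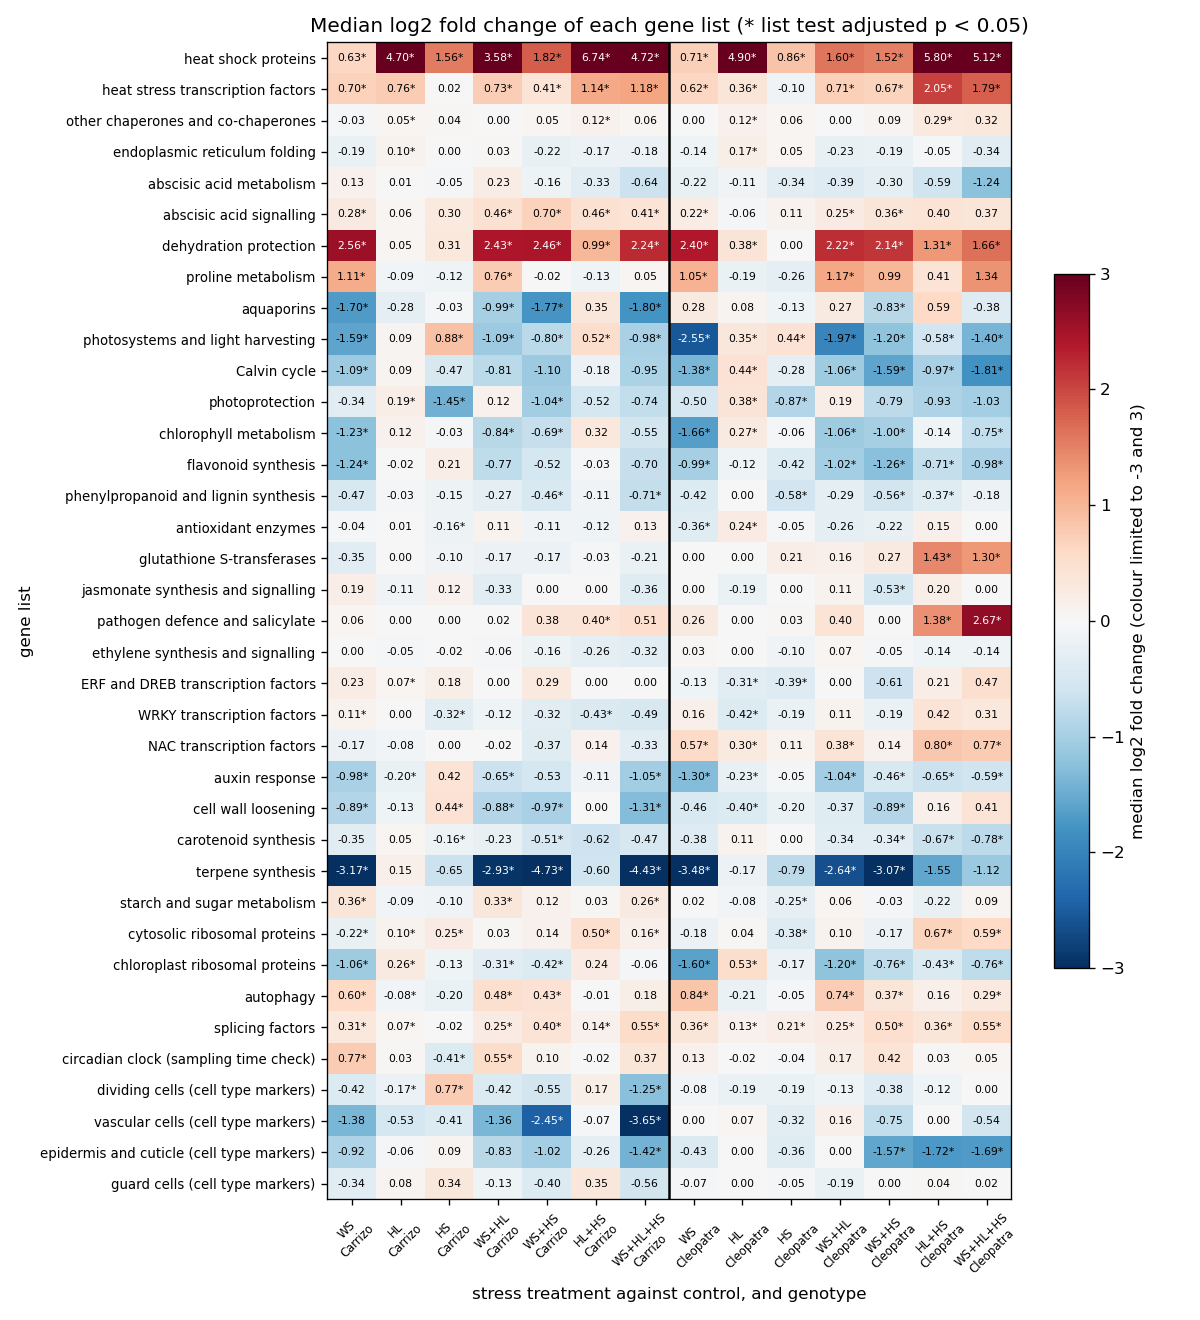
Median log2 fold change against CT of 37 gene lists under 7 stresses in Car (left) and Cleo (right), printed in each cell and shown by colour, red above 0 and blue below; an asterisk marks lists called at an adjusted p below 0.05 with the preset correlation. The heat shock proteins show medians of 4.70 in Car and 4.90 in Cleo under HL and 6.74 and 5.80 under HL+HS.

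WS+HL+HS changed the most genes. HSP70 LOC102625888 went from 2.18 ± 0.583 to 2659 ± 51.6 CPM in Car (10.25 ± 0.16), beside LOC102626248 (10.50 ± 0.29) and LOC102613214 (10.22 ± 0.23). In Cleo LOC102630544 (4899 ± 709 against 0.652 ± 0.0570 CPM, 12.87 ± 0.32) and HSP83-like (LOC102616579, 11.95 ± 0.22) rose most after BAG6 (LOC102629351, 365 ± 37.4 CPM), whose ratio to CT was 18890 (95% counting interval 6462 to 91580). Falls in Car were largest for S2-like (LOC102611808, -7.87 ± 0.53), caffeic acid methyltransferase-like LOC102619425 (-7.39 ± 0.29) and germacrene D synthase-like LOC102623066 (0.569 ± 0.323 against 94.8 ± 19.4 CPM, -7.38 ± 0.25). In Cleo they were largest for a pectinesterase (LOC102610266, 0.347 ± 0.197 against 78.9 ± 11.5 CPM, -7.84 ± 0.20), proline-rich protein 4-like (LOC102619149, -7.69 ± 0.47) and a 36.4 kDa proline-rich protein (LOC102629769, -6.56 ± 0.21), genes of the cell wall. Each had an adjusted p of 3.06e-15 or lower.

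Most heat shock proteins rose here too: in Car 54 of 62 rose and 4 fell (median 4.72, 4.43 at the floor, adjusted p = 1.66e-22). In Cleo 55 rose and 4 fell (median 5.12, 4.79 at the floor, adjusted p = 3.9e-19). Of the dehydration protection genes, in Car 23 of 36 rose and 3 fell (median 2.24, adjusted p = 1.51e-06). In Cleo 25 rose and 5 fell (median 1.66, adjusted p = 7.59e-05, adjusted p = 0.0846 estimated). In Car aquaporins fell (1 of 31 rose and 23 fell, median -1.80, -1.70 at the floor, adjusted p = 3.32e-05, adjusted p = 0.093 estimated), as did terpene synthases (3 of 33 rose and 27 fell, median -4.43, -3.81 at the floor, adjusted p = 4.57e-05, adjusted p = 0.066 estimated) and cell wall loosening genes (20 of 138 rose and 82 fell, median -1.31, adjusted p = 0.000363, adjusted p = 0.0857 estimated), with expansin-A4 (LOC102621431) at -6.67 ± 0.22. Markers of dividing cells (14 of 87 rose and 57 fell, median -1.25, adjusted p = 0.00811, adjusted p = 0.243 estimated) and vascular cells (1 of 41 rose and 31 fell, median -3.65, adjusted p = 4.69e-05, adjusted p = 0.0724 estimated) fell in the same Car libraries, among them cyclin-D1-1 (LOC102622171, -4.26 ± 0.20) and a sieve element occlusion gene (LOC102630205, -3.65 ± 0.23). Epidermis and cuticle markers fell in both genotypes: in Car 4 of 25 rose and 19 fell (median -1.42, adjusted p = 0.0192, adjusted p = 0.455 estimated). In Cleo 6 rose and 18 fell (median -1.69, adjusted p = 0.0192, adjusted p = 0.455 estimated). In Cleo pathogen defence genes rose (37 of 60 rose and 15 fell, median 2.67, 2.04 at the floor, adjusted p = 0.00315, adjusted p = 0.0834 estimated), with PR-4A (LOC102578030) at 3239 ± 373 against 40.3 ± 15.1 CPM (6.33 ± 0.21). Cytosolic ribosomal proteins also rose in Cleo (123 of 168 rose and 6 fell, median 0.59, adjusted p = 1.55e-07, adjusted p = 0.58 estimated). Photosystem genes fell: in Car 1 of 39 rose and 33 fell (median -0.98, adjusted p = 1.97e-05, adjusted p = 0.535 estimated). In Cleo 1 rose and 36 fell (median -1.40, adjusted p = 3.33e-09, adjusted p = 0.383 estimated). Of the Calvin cycle genes in Cleo, 3 of 15 rose and 12 fell (median -1.81, adjusted p = 0.0037, adjusted p = 0.439 estimated), but a rubisco activase (LOC102630057) stood at 4436 ± 94.7 against 39.0 ± 2.16 CPM.

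In Car 7710 genes were higher and 9174 lower (15563 called in unmarked libraries), and in Cleo 8889 genes were higher and 8320 lower (16878 in unmarked libraries). The Cleo libraries also held the highest ribosomal RNA share. The genotypes differed in 13388 genes (12727 in unmarked libraries). Extensin-like EPR1 (LOC102617583, 8.99 ± 0.31) and UGT76B1-like (LOC102606711, 7.59 ± 0.26) were higher in the Cleo response, and Kunitz trypsin inhibitor 2 (LOC102622270, -5.66 ± 0.20) was lower. Of the cell wall loosening genes 64 of 138 were higher and 16 lower (median 3.04, 2.78 at the floor, adjusted p = 1.33e-06) in Cleo, of the vascular markers 20 of 41 were higher and 2 lower (median 3.33, 2.90 at the floor, adjusted p = 0.00167, adjusted p = 0.205 estimated) and of the dividing-cell markers 42 of 87 were higher and 8 lower (median 0.68, adjusted p = 0.00351, adjusted p = 0.233 estimated). The departure of the triple combination from its single and pairwise parts was called in 4168 genes in Car, where all HS libraries are marked, and 5996 in Cleo (6782 in unmarked libraries). In Car WRKY53 (LOC102614924, 5.27 ± 0.35) and a lipoxygenase 3-1-like gene (LOC102622489, 3.95 ± 0.36), of jasmonate synthesis, were above the parts, and cellulose synthase A8 (LOC102629226, -3.57 ± 0.84) and arabinogalactan protein FLA12 (LOC102611245, -3.41 ± 0.81) below. In Cleo HSP70-5-like (LOC102625591, 6.88 ± 0.30) and a GDSL esterase APG-like gene (LOC102617518, 5.93 ± 0.64) were above, and NAC29 (LOC102608057, -5.77 ± 0.21), asparagine synthetase 1 (LOC102628580, -5.61 ± 0.26) and PP2C 25 (LOC102628871, -4.89 ± 0.22) below. Of the heat shock proteins 40 of 62 were higher and 2 lower (median 2.13, 1.96 at the floor, adjusted p = 1.01e-26) in Cleo. Vascular (2 of 41 higher, 14 lower, median -1.57, -1.39 at the floor, adjusted p = 0.000493, adjusted p = 0.156 estimated) and epidermis markers (0 of 25 higher, 4 lower, median -0.83, adjusted p = 0.00432, adjusted p = 0.394 estimated) were below the parts in Car, and in Cleo clock genes (0 of 22 were higher and 11 lower, median -0.45, adjusted p = 9.72e-07, adjusted p = 0.11 estimated) were below and epidermis markers (11 of 25 higher, 2 lower, median 1.47, adjusted p = 0.00426, adjusted p = 0.394 estimated) above.

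Without stress, in the CT libraries, Cleo was set against Car. F-box PP2-B15-like (LOC112497515) stood at 724 ± 105 against 2.44 ± 1.43 CPM (8.21 ± 0.26), endochitinase-like LOC102627878 at 405 ± 105 against 2.01 ± 0.743 CPM (7.64 ± 0.24) and wound-induced proteinase inhibitor 1-like (LOC102630850) at 339 ± 217 against 2.04 ± 0.502 CPM (7.37 ± 0.35), which varied between Cleo libraries. BAG6 (LOC102629351) held 3 counts in Cleo and 242 ± 14.6 CPM in Car, where the ratio of Car to Cleo was 12450 (95% counting interval 4262 to 60400). The 21 kDa seed protein-like genes LOC102606769 (0.167 ± 0.0837 against 1148 ± 282 CPM) and LOC107175685 (0.0638 ± 0.0267 against 409 ± 98.7 CPM) were also near 0 in Cleo, at -12.72 ± 0.79 and -12.58 ± 0.64. Adjusted p was 2.7e-15 or lower for each. In total 7830 genes were higher in Cleo and 8151 lower, 7692 of them at least 2-fold. Unmarked libraries alone called 14336 genes and marked ones 14062, where Car and Cleo, in that order, kept 1 library.

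Last, the changes of Car and Cleo under the same stress were compared across 23721 genes, which are not independent replicates. No control library is shared between the genotypes. Pearson's r of the log2 fold changes was 0.57 for WS, 0.529 for WS+HL, 0.52 for WS+HS, 0.419 for HL+HS, 0.402 for WS+HL+HS, 0.317 for HL and 0.235 for HS, and Spearman's rho was 0.645, 0.598, 0.581, 0.439, 0.471, 0.363 and 0.34 in that order. Under WS 5362 genes rose in both genotypes, where independent lists would share 2187, and 5789 fell in both (2804). Calls in opposite directions numbered 948 under WS, 245 under HL, 1945 under HS and 2560 under WS+HL+HS. Under HL 1455 rose in both (406) and 1163 fell in both (375). Under HS 3637 rose (2073) and 3277 fell (1714).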

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

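The tests of exchanged labels, of the column mark and of ribosomal RNA, and the splits for the stress comparisons, the CT comparison and the genotype differences, were chosen only after the results were seen. The responses of the genotypes differed, by a test of the difference itself, in 8557 genes for WS, 3659 for HL, 10370 for HS, 9494 for WS+HL, 9888 for WS+HS, 11873 for HL+HS and 13388 for the triple stress. Genes that follow differed by the same test, given as log2 differences, Cleo minus Car.

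BAG6 (LOC102629351) stood at 11.62 for HL, 7.02 for HS, 8.43 for WS+HS, 11.86 for HL+HS and 11.37 for the triple stress. They rest on 3 Cleo control counts and depend on the prior count. In every treatment BAG6 CPM was lower in each Cleo library than in any Car library (HL, at most 273.6 against 780). UGT76B1-like (LOC102606711) stood at 8.21 for WS, 7.98 for WS+HL, 7.56 for WS+HS and 7.59 for the triple stress. The aquaporin PIP2-2-like LOC102608729 stood at 6.68 for WS and 5.85 for WS+HL, its relative LOC102609769 at 5.44 for WS, and NRT1/PTR 3.1-like (LOC102609680) at 4.66 for HS and 6.82 for HL+HS. Also higher in the Cleo response were beta-amyrin synthase-like (LOC102612414, 5.70 for HS), a caffeic acid methyltransferase-like gene (LOC102619425, 5.84 for WS+HL), germacrene D synthase-like (LOC102623066, 7.41 for WS+HS), TSJT1-like (LOC102609704, 9.66 for HL+HS) and extensin-like EPR1 (LOC102617583, 8.99 for the triple stress). Lower were inositol oxygenase 1 (LOC102618274, -5.45 for WS and -5.51 for WS+HL), asparagine synthetase 1 (LOC102628580, -5.72 for WS) and a suppressor of disruption of TFIIS (LOC102622497, -4.78 for WS). Kunitz trypsin inhibitor 2 (LOC102622270) stood at -4.32 for HS, -5.31 for HL+HS and -5.66 for the triple stress, seed lectin-like (LOC102628131) at -5.74 for WS+HS and -5.43 for the triple stress, and endochitinase-like (LOC102628172) at -5.87 and -5.29. WRKY53 (LOC102614924) stood at -4.10 for HL, a salicylate methyltransferase-like gene (LOC102625129) at -4.55 and chlorophyllase-1 (LOC102621972) at -4.34 for HS. A 17.4 kDa heat shock protein (LOC102626248) stood at -4.63 and chalcone synthase 2-like (LOC102607309) at -4.58 for WS+HL, strictosidine synthase-like 4 (LOC102608831) at -5.48 for WS+HS, and a lectin (LOC102630138) at -5.81 and proline-rich protein 4-like (LOC102619149) at -5.75 for HL+HS.

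For HL, the 21 kDa seed protein-like genes LOC102606769 (4.54) and LOC107175685 (4.39) stood at 0.25 and -0.13 without HL-Cleo replicate 3. The 5.8S ribosomal RNA genes LOC112495954 (-3.34) and LOC112495819 (-3.29) were no longer called without CT-Car replicate 1 (-3.29 and -3.23) or 2 (-3.02 and -2.96), HL-Car replicate 3 (-1.98 and -1.99), CT-Cleo replicate 3 (-1.50 and -1.53) or HL-Cleo replicate 1 (-3.28 and -3.22) or 3 (-3.27 and -3.23), and the second also without HL-Cleo replicate 2 (-3.42).

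Heat shock proteins rose more under HL than under HS in both genotypes. In Cleo no library of HL or HS is marked, so the mark does not part them. In Car the mark as the whole source is argued against by the median difference of the list with the mark as a term, 2.14 (camera with an estimated correlation, p = 3.9e-05 in this 1 test). Exchanged HL and HS labels remain possible: photoprotection genes were higher under HL, by a median of 1.22 in Cleo and 1.57 in Car, but this list holds 9 genes and gave adjusted p of 0.219 and 0.209 with an estimated correlation. Leaf temperature under HL and the length of each stress are not given, so a biological difference was not tested.

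The departure of HL and HS from additivity was called in more genes in Cleo than in Car. Without ribosomal RNA and chloroplast genes the ratio was 1.794, which cannot test library quality. With the mark as a term, its effect taken from the 6 groups with both kinds, the genotype difference of the departure was called in 8254 genes (8531 without the term, 7882 to 8835 with 1 library left out). This argues against a mark effect common to all groups as the whole source of that difference. The ratio of the counts fell to 1.498 (11375 against 7592 genes, 11864 against 6599 without the term), so a part of the excess in Cleo from the mark stays open. So does a mark effect peculiar to HS in Car, where no library is unmarked. A biological difference between the genotypes stays open too.

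Of 4693 genes at least 2-fold lower in Cleo than in Car under CT, 988 (21.1%) reached the Car control level in a Cleo stress group. A gene that loses reads in alignment to the sweet orange reference can still reach that level once a stress raises it, so this share decides nothing, and such loss and lower expression cannot be told apart here.

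Other splits of the libraries were refitted with the libraries of each comparison alone. For 3 against 3 libraries the 10 splits are too few for a share under 0.05. The real split alone (1 of 10) reached its count in each: 14817, 1118, 13571, 13995, 15402, 14001 and 16313 genes in Car and 14006, 7252, 11587, 13895, 14251, 13729 and 15359 in Cleo, for WS, HL, HS, WS+HL, WS+HS, HL+HS and the triple stress, 13501 for Cleo against Car, and 12355 and 13235 for HL against HS in Car and Cleo. The highest other split gave 0 genes except for HL in Car, where it gave 767 and set the 3 marked libraries against the 3 unmarked. Other splits mix treatments and so do not model equal or additive responses. Chance was thus excluded for no difference or departure. Under HL the genotypes differed in 1790 genes (highest other 5306, 6 of 100 splits as large). WS gave 7517 (7195), HS 9595 (13871, 2 of 100) and WS+HL 8258 (7646). WS+HS gave 9366 (6069), HL+HS 10304 (7504) and the triple 12185 (16780, 2 of 100). Why some splits called more genes was not tested. In HL, HS and the triple, 1 split as large exchanged stress and control in 1 genotype, turning a difference of responses into their sum. In Car, departures of WS and HL gave 2074 (18), WS and HS 9446 (6581) and HL and HS 5431 (12711, 2 of 100). The triple gave 4492 (3627). Cleo gave 5761 (6252, 2 of 100), 8853 (1809), 11095 (6254) and 5815 (1) in this order. The genotype difference of the HL and HS departure gave 7469 (3255).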

How the results depend on the processing

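The settings that use the column mark, and the removal of ribosomal RNA and chloroplast genes, were chosen only after the results were seen. All 33 counts of called genes stayed within 1.5 times the reported count with DESeq2 size factors (0.962 to 1 times), without the filter on low counts (0.947 to 1), with the mark as a term (0.794 to 1.3), without ribosomal RNA and chloroplast genes (0.973 to 1.01) and by the DESeq2 Wald test (0.985 to 1.18). Of 26 counts that unmarked libraries could give, 9 with at least 2 libraries in each group lay at 0.981 to 1.1 times the reported ones. The other 17 (0.733 to 1.13 times) rest on a lone library of CT in Car or HL+HS in Cleo, assumed to vary like the other groups. The share of higher genes among the calls moved by at most 14.2 percentage points with only the libraries of the comparison, 11.1 in marked libraries and 6.7 in the settings above. At least 24.6% of the reported calls of a comparison were kept in the first, 43.1% in the second, 60.4% in unmarked libraries, 72.8% with the mark as a term and 91.9% in the others above. With only the libraries of the comparison 3 of 33 counts moved beyond 1.5 times: 1118 genes for HL in Car (4379 reported, 1078 of the reported calls kept), 1790 for the genotype difference under HL (3659, 1704 kept) and 2074 for the departure of WS and HL in Car (4301, 1935 kept). Marked libraries alone gave 2810 genes for HL in Car, with 1 HL library. Of their other 6 counts, all within 1.5 times, 5 also rest on a lone library and 1 of these sets 1 library against 1. Of 330 counts with 1 library left out, 1 moved further: the departure of WS and HL in Car. It ranged from 2916 to 6760 genes, the highest without HL-Car replicate 1, the only marked HL library of Car. In each of these cases the cause was not tested.

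Pearson's r between the genotypes' log2 changes, taken across genes that are not independent replicates, was higher when only genes called in at least 1 genotype entered, at 0.616 for WS, 0.467 for HL, 0.266 for HS, 0.574 for WS+HL, 0.563 for WS+HS, 0.444 for HL+HS and 0.416 for the triple stress. Leaving out 1 library gave 0.551 to 0.567, 0.270 to 0.306, 0.216 to 0.235, 0.511 to 0.526, 0.503 to 0.518, 0.393 to 0.423 and 0.383 to 0.412 in the same order. With the mark as a term r was 0.223 for HS (0.235 reported) and 0.408 for HL+HS (0.419 reported), and the cause was not tested.

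Of 1709 values of single genes, 0 lost a call or turned with DESeq2 size factors, by the Wald test or with the mark as a term. With only the libraries of the comparison 39 lost their call, in marked libraries alone 12, in unmarked libraries alone 11, without the filter 1 and without ribosomal RNA and chloroplast genes 1, and 44 of the values with 1 library left out. Of the genes that turned, fasciclin-like arabinogalactan protein 12 (LOC102610633), a vascular marker, fell in Car under HL (-2.65) and stood at 0.49 in unmarked libraries, of which CT has 1. The 21 kDa seed protein-like gene LOC107175685 was higher in the Cleo response to HL (4.39) and ranged from -0.13 to 5.06 with 1 library left out, the lowest without HL-Cleo replicate 3. The cause of either was not tested. Of 443 list calls 371 were lost with the estimated correlation and 72 held, and 14 were lost with the mark as a term, 8 without the filter, 7 without ribosomal RNA and chloroplast genes and 6 with the size factors. Leaving out 1 library at a time ended 172 of these calls and kept 4310.

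The replicate numbers did not pair the libraries. Deviations from group means of libraries with the same number correlated at a mean r of 0.00527 (lowest -0.195, 6 of 360 pairs over 0.1), against -0.00261 for different numbers, and 19 of the 48 libraries correlated best with their own number. As a block, the number moved the 33 counts to 0.991 to 1.01 times the reported ones and ended 3 gene calls and 2 list calls. Depth limits low genes: 3089 genes had 0 counts in every library, and a change between levels of at most 3 counts per group was not detectable.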

Other observations

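The list tests of the genotype differences were chosen only after results had been seen. Splicing factors, which remove introns from transcripts, moved upward in nearly every stress. The list test called the 67 genes in 13 of the 14 stress comparisons, all but HS in Car (23 rose and 18 fell, median -0.02, adjusted p = 0.988). None of the 13 calls held with an estimated correlation, where adjusted p ranged from 0.135 to 0.517. Under WS 45 rose and 3 fell in Car (median 0.31, adjusted p = 3.01e-05), and 43 rose and 6 fell in Cleo (median 0.36, adjusted p = 0.000812). Medians were highest under the triple stress, at 0.55 in Car (40 rose and 15 fell, adjusted p = 0.000164) and 0.55 in Cleo (43 rose and 5 fell, adjusted p = 0.000209). Under it the serine/arginine-rich factor SCL33 (LOC102626112) rose by 1.84 ± 0.05 in Car and 2.56 ± 0.06 in Cleo, and SLU7-like (LOC102607788) by 2.09 ± 0.10 and 2.52 ± 0.10. The HL+HS call in Car gave adjusted p = 0.0504 without CT replicate 3 and 0.075 with the column mark as a term, and the HS call in Cleo gave 0.0605 without CT replicate 3.

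Clock genes were also called in Car under WS (13 of 22 rose and 6 fell, median 0.77, adjusted p = 0.00244, and adjusted p = 0.287 with an estimated correlation) and WS+HL (13 rose and 6 fell, median 0.55, adjusted p = 0.00608 and 0.345). Under WS in Car REVEILLE 1 (LOC102630458) rose by 2.12 ± 0.05 and GIGANTEA (LOC102626780) by 1.79 ± 0.07. The genotype difference of the list was called under WS (3 higher and 13 lower in the Cleo response, median -0.42, adjusted p = 0.000668 and 0.254), HS (12 higher and 3 lower, median 0.37, adjusted p = 0.00104 and 0.275) and the triple stress (5 and 14, median -0.37, adjusted p = 0.0248 and 0.448). Times of sampling are not given in the sources used here.

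The fall of GDPD1, SPX1 and purple acid phosphatase 8-like under HL raised the hypothesis that phosphate starvation genes fell together. A list of 56 other phosphate-linked genes, drawn from descriptions before its result was seen, was tested with camera. In Car 1 rose and 21 fell (median -0.24), and in Cleo 4 rose and 28 fell (median -0.33). Adjusted p over both was at most 2.43e-05 (6.76e-05 with an estimated correlation). The list is wider than starvation genes and was not rerun with the mark or a library left out. Phosphate was not analysed.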
